A study of Mus musculus with 16 samples.

How the data were processed

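Polyadenylated RNA from whole trigeminal ganglia of mice was sequenced from stranded libraries, per the labels' protocols. There were 16 libraries in 4 groups of 4: wild-type (WT) animals and animals lacking Nogo-A (KO), on day 14 of embryonic life (E14) or 25 days after birth (P25). Groups and replicate numbers were taken from the sample titles. Each library came from 1 ganglion, per the labels.

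The deposited values are estimated counts per gene, which the authors gave as whole numbers. The submitters' processing notes name fastp 0.20.0, kallisto 0.46, DESeq2 1.32.0 and the GRCm39 assembly. The notes give no role or order for these tools, and the strand setting of the counting and the transcript annotation are not given in the sources used here. Estimated counts share reads among similar transcripts by a model, so genes with a near-identical copy are less certain than the counts alone show. A gene-level value adds all transcripts of a gene, so a deletion that removes some transcripts of a gene need not lower its total.

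Each library listed the same 25719 gene identifiers, of which 25614 had a symbol in the gene name table. Gene positions, transcript length and GC content came from an annotation of GRCm38, which is not the assembly named in the processing notes. Positions are therefore given as GRCm38 positions and were used for neighbourhood questions only. Library totals ran from 15532373 to 29562379 counts. Counting intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

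Differential expression was computed in R 4.3.3 with edgeR 4.0.16: TMM scaling, the filterByExpr filter on the 4 groups, 1 fit to all 16 libraries with a mean per group, and the quasi-likelihood F test with Benjamini-Hochberg adjustment. The filter left 15109 genes. Genes with an adjusted p under 0.05 are said to be called. All adjusted p-values for genes come from this test unless another tool is named. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are CPM, computed with the TMM-scaled library totals, with the standard deviation (SD) over 4 libraries. The p-values measure the spread between ganglia. The labels state 4 animals per group, but the names of 2 pairs of E14 libraries carry the same number with R and L, so some E14 ganglia may share an animal.

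A set of 46 gene lists for pathways and cell types was written down before the data were examined, and 44 of them had at least 3 tested genes. Lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, and again with the correlation estimated from the data. The rule for named genes was also fixed then. It took Rtn4, up to 8 called genes each way with all KO libraries on 1 side of all WT libraries and a mean of at least 1 CPM, a fill to 10 genes by lowest unadjusted p under the same symbol and level limits, and leading members of the called lists. For the stage comparison it took the 5 largest changes each way at a mean of at least 10 CPM and up to 2 called members per list. Unnamed gene models and pseudogenes were left out by their symbols, and a few genes that the rule took are not reported here.

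Where a group had no counts, the fold is a bound computed with 3 counts over the whole group. Where a group had 1 to 3 counts, the ratio of scaled counts is given with its exact 95% counting interval. Genes called at both stages were compared with chance by a one-sided Fisher's exact test, and genes within 20 Mb of Rtn4 with the rest by a two-sided one.

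The fit was tested on simulated counts drawn from the means, dispersions and totals of these libraries with 200 genes changed. In the simulated E14 genotype comparison, with 14993 genes, 54% of the genes changed 2-fold and 100% of those changed 4-fold were called with the right sign, and 6 of 136 calls were false. In the simulated P25 genotype comparison, with 15004 genes, these shares were 60% and 100%, and 9 of 145 calls were false. In the simulated stage comparison in WT, with 14981 genes, the shares were 48% and 94%, and 6 of 130 calls were false. Of genes changed 1.5-fold, 8% were called at E14 and 12% at P25. Only genes with a mean of at least 1 CPM were changed. The simulated genes were drawn independently, without a trend on GC content or length and without an outlying library. These shares need not hold for the real libraries.

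The alternatives planned before the data were examined were DESeq2 1.42.0, RLE scaling, library totals alone, no and a stricter low-count filter, a replicate block, summing of same-numbered ganglia, a Y-linked covariate, a fit to the compared libraries only, leaving out each library in turn, an estimated correlation, the fry set test, and other windows around Rtn4. Offsets for transcript GC content and length, and robust dispersions, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.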

Results

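The trigeminal ganglion holds the cell bodies of sensory neurons that serve the face, together with satellite glia, Schwann cells, vessels and immune cells. Nogo-A is the long protein made from Rtn4 and is known as an inhibitor of neurite growth. Gene expression was measured in ganglia of wild-type (WT) mice and mice lacking Nogo-A (KO). Ganglia were taken on day 14 of embryonic life (E14) or 25 days after birth (P25), with 4 libraries per group. Library totals averaged 19198517 counts in E14 WT (SD 1953586, n = 4) and 18474664 in E14 KO (SD 2816425, n = 4). They averaged 26502566 in P25 WT (SD 2337729, n = 4) and 23773056 in P25 KO (SD 1074976, n = 4). The lowest library held 15532373 counts and the highest 29562379.

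The targeted gene was examined first. Rtn4 (ENSMUSG00000020458, GRCm38 chromosome 11, 29692947 to 29744331) stood at 360 ± 164 CPM (SD, n = 4) in E14 WT and 298 ± 74.7 CPM in E14 KO. In P25 ganglia it stood at 489 ± 58.7 CPM in WT and 368 ± 17.9 CPM in KO. The log2 fold change was -0.27 (SE 0.26, edgeR adjusted p = 0.943) at E14 and -0.41 (SE 0.26, edgeR adjusted p = 1) at P25. At E14 the WT libraries read 328, 144, 521 and 444 CPM and the KO libraries 291, 405, 260 and 236 CPM. At P25 the WT libraries read 494, 542, 512 and 406 CPM and the KO libraries 364, 380, 345 and 384 CPM. All P25 KO libraries thus lay below all P25 WT libraries, although the gene was not called, while the genotypes overlapped at E14. The gene total includes the shorter Nogo-B and Nogo-C transcripts, so these values do not isolate the Nogo-A transcript and do not check the KO labels.

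At E14 few genes differed between the genotypes. Lgals7 (ENSMUSG00000053522, GRCm38 chromosome 7, 28863853 to 28866284), which encodes the epithelial lectin galectin-7, fell from 23.6 ± 4.48 CPM (SD, n = 4) in WT to 4.46 ± 2.07 CPM in KO, a log2 fold change of -2.40 (SE 0.36, edgeR adjusted p = 0.0111). Rnf167 (GRCm38 chromosome 11, 70647235 to 70651421), which encodes an endolysosomal ubiquitin ligase, fell from 76.2 ± 23.4 to 33.1 ± 3.67 CPM, a log2 fold change of -1.20 (SE 0.20, adjusted p = 0.0278). For each of these genes all 4 KO libraries lay below all 4 WT libraries. They were among the 3 genes called at E14, all lower in KO, out of 15109 tested, and 735 genes had an unadjusted p under 0.05 where 755 would be expected by chance. DESeq2 called 6, all lower in KO, among them Lgals7, Rnf167 and Spaca6. The E14 count was 1 without E14 WT replicate 1, E14 KO replicate 1, 2 or 3, or P25 KO replicate 4, where neither Lgals7 nor Rnf167 was called, and 5 without E14 WT replicate 2. Rnf167 was also lost without E14 KO replicate 4 (adjusted p = 0.0874), without P25 WT replicate 1 or 2 or P25 KO replicate 2 (0.0503, 0.0543 and 0.0573) and in the fit to the E14 libraries alone (0.582). Of the E14 libraries, 2 WT and 2 KO libraries share a number between left and right ganglia.

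Below that threshold, the genes with the lowest unadjusted p at E14 included several expressed by macrophages. Csf1r, the receptor for colony stimulating factor 1, stood at 26.9 ± 5.78 CPM in WT and 15.9 ± 3.91 CPM in KO (adjusted p = 0.654). Laptm5 stood at 15.6 ± 3.11 and 8.80 ± 1.53 CPM (adjusted p = 0.427), Itgam, which encodes the integrin CD11b, at 1.91 ± 0.404 and 0.870 ± 0.194 CPM (adjusted p = 0.549), and Aif1 at 1.28 ± 0.373 and 0.521 ± 0.300 CPM (adjusted p = 0.942). In the macrophage list 17 of 20 genes were lower in KO. None was called over all genes and 3 were called when adjusted over the list alone (camera adjusted p = 5.19e-05, adjusted p = 0.628 with an estimated correlation). The list mean, as log2 deviation from the stage mean, was 0.63, -0.34, -0.09 and 0.59 in the WT libraries and -0.19, -0.26, -0.12 and -0.22 in the KO libraries, so WT replicate 2 lay below all 4 KO libraries. The median log2 fold change of -0.42 was -0.23 without WT replicate 1, -0.26 without WT replicate 4 and -0.24 without KO replicate 2. Spaca6 at 9.04 ± 2.04 and 4.08 ± 0.565 CPM and Arsg at 6.74 ± 0.604 and 3.72 ± 0.865 CPM were also lower in the KO libraries, and Dpy30 was higher at 24.9 ± 4.76 and 50.6 ± 21.1 CPM, with adjusted p-values of 0.362, 0.654 and 0.549. DESeq2 called Spaca6 (adjusted p = 0.0187). Arhgap33os read 0.594 ± 0.703 CPM in WT and 2.85 ± 1.07 CPM in KO (adjusted p = 0.427). It is antisense to its neighbour and the strand setting of the counting is not stated, so its value is uncertain. It was called without E14 WT replicate 2, with an adjusted p of 0.00178 for Arhgap33os.

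A further 6 lists were called at E14 by camera with the preset correlation, and none with an estimated correlation. All 52 cytosolic ribosomal protein genes had a positive log2 fold change, with a median of 0.38 (camera adjusted p = 5.92e-19), as did 45 of 48 nuclear genes of oxidative phosphorylation, with a median of 0.21 (camera adjusted p = 1.51e-07). With an estimated correlation these adjusted p-values were 0.628 and 0.878. The median of 0.21 was 0.34 without WT replicate 4 or KO replicate 2 and 0.13 without KO replicate 1. Rpl11 stood at 328 ± 56.3 and 512 ± 213 CPM, Rpl32 at 365 ± 76.2 and 550 ± 187 CPM, Ndufa1 at 32.3 ± 5.83 and 49.8 ± 18.2 CPM, and Uqcrb at 22.8 ± 3.08 and 31.8 ± 9.68 CPM in WT and KO. Of 13 mitochondrially encoded genes 11 were higher in KO (adjusted p = 0.0144, or 0.900 with an estimated correlation), among them mt-Nd1 at 1214 ± 603 and 1924 ± 775 CPM and mt-Nd2 at 641 ± 311 and 1022 ± 481 CPM. Interferon-stimulated genes were higher for 18 of 24 members (adjusted p = 0.00462, or 0.900 with an estimated correlation). Xaf1 stood at 0.443 ± 0.174 and 0.856 ± 0.170 CPM, and Gbp3 had 6 counts over the WT and 23 over the KO group. The 3 melanocyte genes tested were higher (adjusted p = 0.00832, or 0.483 with an estimated correlation), with Tyrp1 at 1.22 ± 0.532 and 2.81 ± 0.995 CPM and Mitf at 0.799 ± 0.465 and 1.18 ± 0.481 CPM. Tyrp1 is also a member of the satellite glia list, so this result does not single out melanocytes. Extracellular matrix genes were lower for 33 of 36 members (adjusted p = 0.00351, or 0.900 with an estimated correlation), with Lama1 at 17.1 ± 6.07 and 11.1 ± 2.30 CPM and Fbn1 at 99.9 ± 9.62 and 74.8 ± 10.98 CPM. No member of these 6 lists was called over all genes, and 1, Tyrp1 of the melanocyte list, was called when adjusted over the list alone. E14 WT replicate 2 stood apart from the other libraries, and transcript GC content and length accounted for 50.6% of the variance over genes in its deviation from the stage mean. Without it 3 lists were called in place of 7, and the mitochondrially encoded, interferon, melanocyte and matrix lists had adjusted p-values of 0.961, 0.265, 0.104 and 0.106. Without E14 KO replicate 3, 4 lists were called. The interferon and melanocyte lists were also not called without WT replicate 3 (0.156 and 0.145), KO replicate 2 (0.224 and 0.115) or KO replicate 3 (0.0810 and 0.0542). The mitochondrially encoded list was not called without KO replicate 2 (0.440) or 3 (0.344) or with same-numbered ganglia summed (0.480), nor the matrix list without KO replicate 1 (0.207), and offsets for GC content and length gave them adjusted p-values of 0.0584 and 0.0897.

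Lists close to the known roles of Nogo-A gave no call at E14. The list of Nogo-A ligands and receptors also holds Rtn4 itself and downstream genes such as Gna13 and Arhgef11. It had negative log2 fold changes for 16 of 18 genes, with a median of -0.18 (camera adjusted p = 0.219). Axon guidance genes were negative for 32 of 41 (adjusted p = 0.138), and the RhoA and ROCK pathway had an adjusted p of 0.953. Sensory neuron genes were positive for 17 of 20 (adjusted p = 0.0788), satellite glia genes for 11 of 20 (adjusted p = 0.0951), with 1 gene adjusted over the list alone, and Schwann cell precursor genes for 7 of 19 (adjusted p = 0.831).

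**Figure D1:**
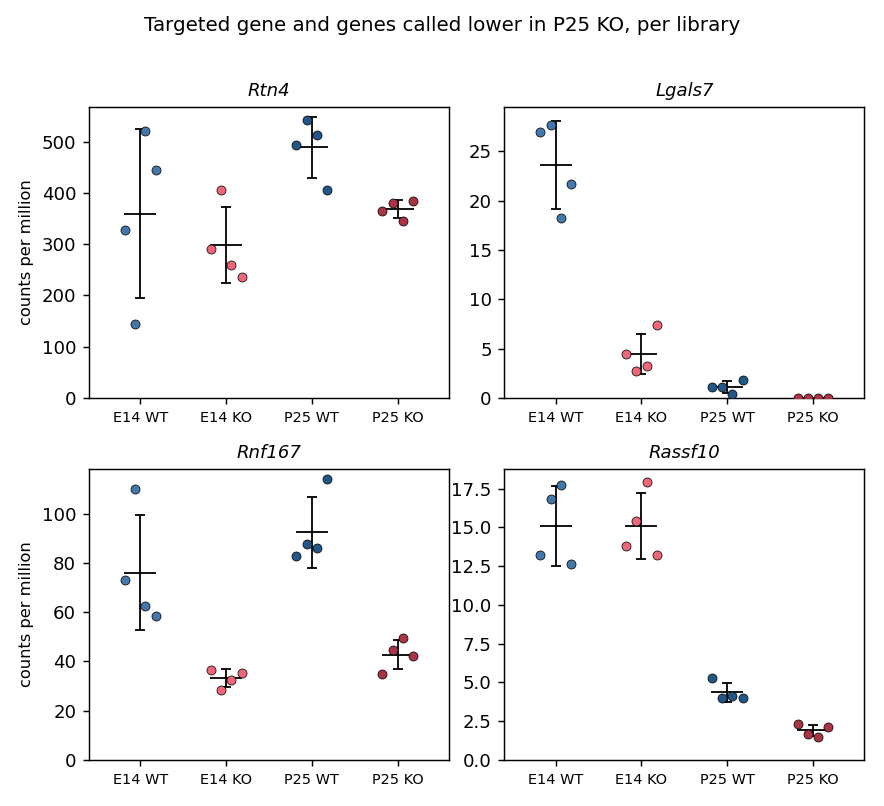
Levels in CPM (vertical axes, from 0) of Rtn4, Lgals7, Rnf167 and Rassf10 in the 4 groups (horizontal axes). Points are libraries, the bar is the group mean and whiskers are the SD. For Rnf167 all KO libraries lie below all WT libraries of their stage, while the Rtn4 total overlaps between WT and KO at E14. At P25 the Rtn4 total lies lower in all KO libraries than in all WT libraries, without a call.

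At P25, genes that are rapidly induced by cell stimulation were higher in KO libraries, and Lgals7 and Rnf167 were lower again. Ccn1, which encodes a secreted matricellular protein, stood at 5.32 ± 1.53 CPM in WT and 208 ± 155 CPM in KO (SD, n = 4), a log2 fold change of 5.29 (SE 0.72, edgeR adjusted p = 0.00218). Zfp36, which encodes an mRNA decay factor, rose from 11.997 ± 3.14 to 45.7 ± 24.2 CPM, a log2 fold change of 1.93 (SE 0.35, adjusted p = 0.0461). Depp1 rose from 2.00 ± 0.669 to 5.89 ± 1.17 CPM, a log2 fold change of 1.55 (SE 0.26, adjusted p = 0.0380). Lgals7 had 110 counts in WT and 1 count in KO, a scaled ratio of 102 with a counting interval of 17.9 to 4053 (adjusted p = 0.00146). Rnf167 fell from 92.6 ± 14.4 to 42.8 ± 6.01 CPM, a log2 fold change of -1.11 (SE 0.19, adjusted p = 0.0411). Rassf10 fell from 4.36 ± 0.615 to 1.90 ± 0.369 CPM, a log2 fold change of -1.19 (SE 0.21, adjusted p = 0.0461). These were among the 7 genes called at P25, 3 higher and 4 lower, and 282 genes had an unadjusted p under 0.05 where 755 would be expected by chance. A count this far below chance can mean that the test was too strict at P25. The few calls therefore do not show that few genes differed.

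The rise of Ccn1 was not seen in each KO library, while for Zfp36 and Depp1 all KO libraries lay above all WT libraries. The KO libraries read 179, 288, 362 and 4.68 CPM and the WT libraries at most 7.13 CPM. Egr1, an immediate early transcription factor, read 548, 516, 431 and 13.6 CPM in the KO libraries, with means of 41.5 ± 15.3 CPM in WT and 377 ± 247 CPM in KO (adjusted p = 0.0734). Fosb stood at 1.19 ± 0.594 and 9.07 ± 5.46 CPM (adjusted p = 0.0642), and Nr4a1 at 47.5 ± 8.90 and 165 ± 92.6 CPM (adjusted p = 0.102). DESeq2 called Egr1, Fosb and Nr4a1, with adjusted p-values of 0.00372, 0.000162 and 0.000734. In the immediate early list 24 of 25 genes were higher in KO, 2 were called over all genes, both higher, and 16 were called when adjusted over the list alone, 15 higher and 1 lower. The lower gene was Ier5, at 8.30 ± 0.685 and 5.18 ± 0.246 CPM, which was chosen after its values were seen. The list was called by camera (adjusted p = 8.49e-39) and held with an estimated correlation (adjusted p = 0.0157). It was not called by the fry set test (adjusted p = 0.186). Its mean over genes was 4.74, 4.89, 4.81 and 3.22 on the log2 CPM scale in the KO libraries and 3.61, 3.28, 3.37 and 3.35 in the WT libraries, so KO replicate 4 lay below all 4 WT libraries. Without KO replicate 4 the count of called genes was 14, of which 12 were higher. It was 4 without P25 WT replicate 1 or E14 KO replicate 1, and 3 without any other P25 library, E14 WT replicate 1 or E14 KO replicate 3, where Lgals7 and Ccn1 were among those left. DESeq2 called 17 genes at P25, and the fit to the P25 libraries alone called 3, among them Arhgap33os and Rnf167, with an adjusted p of 0.111 for Ccn1. Rnf167 and Rassf10 were lost without KO replicate 4, each with an adjusted p of 0.0545, and with a Y-linked covariate Zfp36, Rnf167 and Rassf10 had adjusted p-values of 0.0616, 0.0616 and 0.0588. Rassf10 was also lost with library totals alone (0.0584), with no low-count filter (0.0521) and without E14 WT replicate 3 or 4 or E14 KO replicate 2 or 4 (0.0525, 0.0543, 0.0673 and 0.0695). Zfp36 was lost without E14 WT replicate 3 or E14 KO replicate 1, 2 or 4 (0.0525, 0.0794, 0.0673 and 0.0729), and Rnf167 and Rassf10 without E14 KO replicate 1 (0.0701 and 0.0745). At E14 Ccn1 stood at 3.82 ± 0.738 CPM in WT and 8.88 ± 1.20 CPM in KO. It was not called there, although all 4 E14 KO libraries lay above all 4 E14 WT libraries. Egr1 stood at 20.2 ± 3.56 and 44.4 ± 13.3 CPM at E14. The immediate early list as a whole was not called at E14, with 11 genes higher and 14 lower in KO (camera adjusted p = 0.953).

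**Figure D2:**
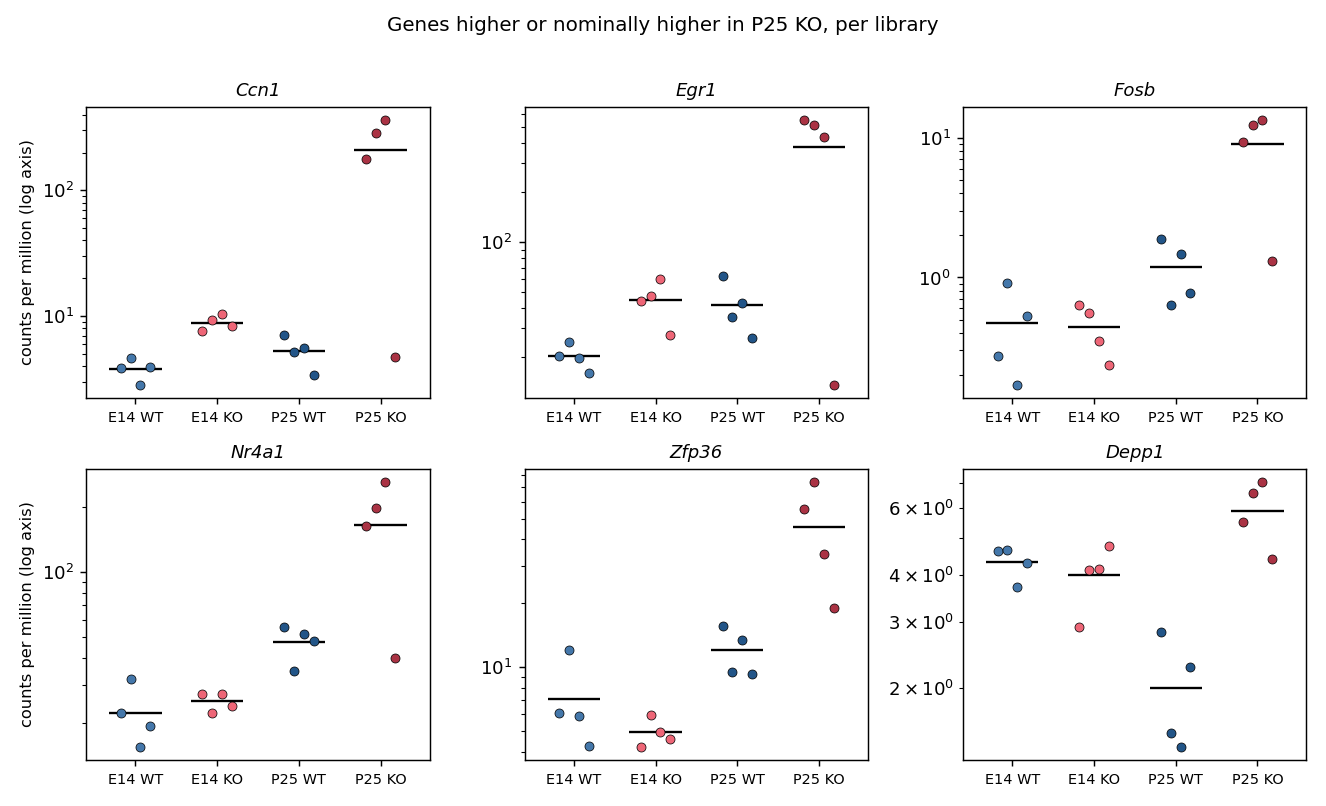
Levels in CPM (vertical log axes) of Ccn1, Egr1, Fosb, Nr4a1, Zfp36 and Depp1 in the 4 groups (horizontal axes). Points are libraries and bars are group means. For Ccn1, 3 P25 KO libraries lie between 179 and 362 and KO replicate 4 lies at 4.68, within the range of the WT libraries.

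Of the other lists at P25, 9 were called by camera, and none of these held with an estimated correlation. Nuclear genes of oxidative phosphorylation were lower in KO for 47 of 48 (adjusted p = 1.73e-06, or 0.651 with an estimated correlation), with Uqcrb at 50.7 ± 7.01 and 40.2 ± 3.21 CPM and Cox6b1 at 310 ± 87.1 and 244 ± 33.8 CPM. Cytosolic ribosomal protein genes were lower for 51 of 52 (adjusted p = 0.000751, or 0.871 with an estimated correlation), with Rpl14 at 205 ± 57.7 and 169 ± 11.9 CPM and Rpl24 at 126 ± 33.6 and 104 ± 12.7 CPM. Heat shock and unfolded protein response genes were lower for 23 of 29 (adjusted p = 0.00741, or 0.456 with an estimated correlation), with Manf at 51.6 ± 6.58 and 41.7 ± 2.60 CPM and Asns at 265 ± 19.5 and 214 ± 35.2 CPM. Mitochondrially encoded genes were higher for 11 of 13 (adjusted p = 0.00441, or 0.651 with an estimated correlation), with mt-Nd5 at 1012 ± 329 and 1448 ± 214 CPM and mt-Atp8 at 0.580 ± 0.166 and 0.926 ± 0.281 CPM. Without WT replicate 4 these 4 lists were not called, with adjusted p-values of 0.776, 0.118, 0.339 and 0.118, and the ribosomal list turned direction. The ribosomal list was also not called without KO replicate 1 (0.129), and offsets for GC content and length ended the call of the ribosomal (0.160), mitochondrially encoded (0.100) and heat shock (0.0866) lists.

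Interferon-stimulated genes were lower in P25 KO for 22 of 24 (camera adjusted p = 0.000156, or 0.651 with an estimated correlation). Isg15 stood at 7.09 ± 8.04 CPM in WT and 2.42 ± 0.719 CPM in KO, and Usp18 at 6.94 ± 10.5 and 1.87 ± 0.266 CPM. Without WT replicate 2 this list turned direction and was not called (adjusted p = 0.284). Genes of central nervous system glia were higher for 12 of 14 (adjusted p = 0.000177, or 0.597 with an estimated correlation), with Ermn at 0.833 ± 0.721 and 1.90 ± 0.831 CPM and Olig2 at 0.447 ± 0.436 and 0.9501 ± 0.473 CPM. Cell cycle genes were higher for 24 of 32 (adjusted p = 0.00121, or 0.614 with an estimated correlation), with Mki67 at 0.801 ± 0.417 and 2.37 ± 0.466 CPM, while Ccne1 stood at 20.02 ± 0.587 and 14.1 ± 2.21 CPM. Erythroid genes were higher for 9 of 11 (adjusted p = 0.000751, or 0.456 with an estimated correlation), with Hba-a1 at 16.2 ± 8.29 and 25.2 ± 4.00 CPM. Hba-a1 has a near-identical copy, so its share of reads is uncertain. Without WT replicate 3 the glial, cell cycle and erythroid lists had adjusted p-values of 0.179, 0.0945 and 0.0867. Endothelial genes were higher for 15 of 18 (adjusted p = 0.000252, or 0.456 with an estimated correlation), with Robo4 at 4.19 ± 0.891 and 6.68 ± 1.62 CPM, while Sox18 stood at 2.85 ± 0.578 and 1.66 ± 0.272 CPM. Without KO replicate 3 the endothelial list had an adjusted p of 0.118. No member of these 9 lists was called over all genes or adjusted over the list alone. The list of Nogo-A ligands and receptors, Rtn4 included (adjusted p = 0.854), axon guidance genes (0.481), sensory neuron genes (0.537) and satellite glia genes (0.772) gave no call. Myelinating Schwann cell genes had an adjusted p of 0.0768, with 1 gene adjusted over the list alone.

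The question whether the KO effect differed between the stages was tested by the interaction. No gene was called by edgeR, where 647 genes had an unadjusted p under 0.05 and 755 would be expected by chance. DESeq2 called 8 genes, all with a higher KO effect at P25, and edgeR called 7 without P25 KO replicate 4. Genes called in both stages numbered 3, among them Lgals7 and Rnf167, all lower in KO, against 0.000794 expected from the sizes of the lists (one-sided Fisher's exact test, p = 6.96e-12). This overlap was 1 without E14 WT replicate 1, without E14 KO replicate 1, 2 or 3, or without P25 KO replicate 4. Both stage tests came from 1 fit with a shared spread estimate for each gene. They are therefore not independent, and the Fisher p may be too small. With an unadjusted p under 0.05 at both stages, 20 genes had the same sign and 15 the opposite sign, where 6.86 would be expected for each. Both counts lay above this number, so the excess of genes with the same sign does not by itself show agreement between the stages. Of 142 tested genes within 20 Mb of Rtn4, none was called by edgeR at E14 or P25 (two-sided Fisher's exact test, p = 1 at each stage), and 6 and 3 had an unadjusted p under 0.05. DESeq2 also called none there. With 3 and 7 genes called in all by edgeR, 0 calls among these 142 genes were likely in any case. The Fisher tests therefore cannot decide on an effect of DNA flanking Rtn4. The shares of genes with an unadjusted p under 0.05 were 4.23% near Rtn4 and 4.87% elsewhere at E14. At P25 they were 2.11% and 1.86%. Rnf167 lies on the same chromosome, 40.9 Mb from Rtn4 in GRCm38. The lists called for a difference between the stages are given among the closing observations.

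Between E14 and P25 the WT ganglion changed broadly, which sets the scale for the genotype effects. Of 15109 genes 9001 were called, 4492 higher and 4509 lower at P25, and 1308 of them changed over 8-fold. Myelin genes rose, with 25 of 26 genes of myelinating Schwann cells called, all higher (camera adjusted p = 1.82e-44, or 0.000404 with an estimated correlation). Mbp, which encodes myelin basic protein, rose from 114 ± 15.1 to 6558 ± 685 CPM (log2 fold change 5.85, SE 0.20, adjusted p = 2.46e-14), and Ncmap from 0.289 ± 0.0336 to 218 ± 18.7 CPM (log2 fold change 9.52, SE 0.24). Satellite glia genes were higher for 16 and lower for 3 called members of 20 (adjusted p = 4.33e-07, or 0.0177 with an estimated correlation). Genes of non-peptidergic nociceptors were higher for 18 and lower for 2 called members of 22 (adjusted p = 1.23e-07, or 0.0427 with an estimated correlation).

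More receptor and channel genes of sensory neurons were called higher at P25 than lower, and members went both ways. Trpm8, the cold-sensing channel, rose from 0.392 ± 0.373 to 211 ± 83.0 CPM, and Chrna6, a nicotinic receptor subunit, from 0.0733 ± 0.0502 to 32.03 ± 1.91 CPM. Of 36 receptor genes of sensory neurons 20 were called higher and 6 lower (adjusted p = 0.000242, or 0.0674 with an estimated correlation). Scn11a, which encodes the sodium channel Nav1.9, rose from 11.5 ± 1.49 to 334 ± 68.0 CPM and Kcns3 from 3.76 ± 0.635 to 90.0 ± 5.84 CPM. Voltage-gated channels were called higher for 25 and lower for 13 of 46 (adjusted p = 0.00289, or 0.495 with an estimated correlation). Low-threshold mechanoreceptor genes were called higher for 12 and lower for 3 of 20 (adjusted p = 8.35e-05, or 0.074 with an estimated correlation). Among 33 synaptic vesicle genes, 17 were called higher and 6 lower (adjusted p = 0.00829, or 0.475 with an estimated correlation), with Vamp1 rising from 31.002 ± 8.23 to 999 ± 52.4 CPM and Sv2b from 38.4 ± 2.87 to 329 ± 59.2 CPM. The largest rises were in Tmem233, with 1 count in the E14 group and 40233 in the P25 group, in Fam178b, with 3 and 14990 counts, and in C4b, Mobp and Myoc, which had no counts in E14 WT. Their bounds were at least 1697-fold higher for complement C4b, 931-fold for the oligodendrocyte gene Mobp and 578-fold for Myoc. The scaled ratio was 30912 for Tmem233, with a counting interval of 5548 to 1221010, and 3839 for Fam178b, with a counting interval of 1313 to 18618. Mobp varied widely between P25 WT libraries (36.0 ± 32.1 CPM), and 10 genes of central nervous system glia were called higher and 1 lower of 14 (adjusted p = 0.0351, or 0.544 with an estimated correlation).

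**Figure D3:**
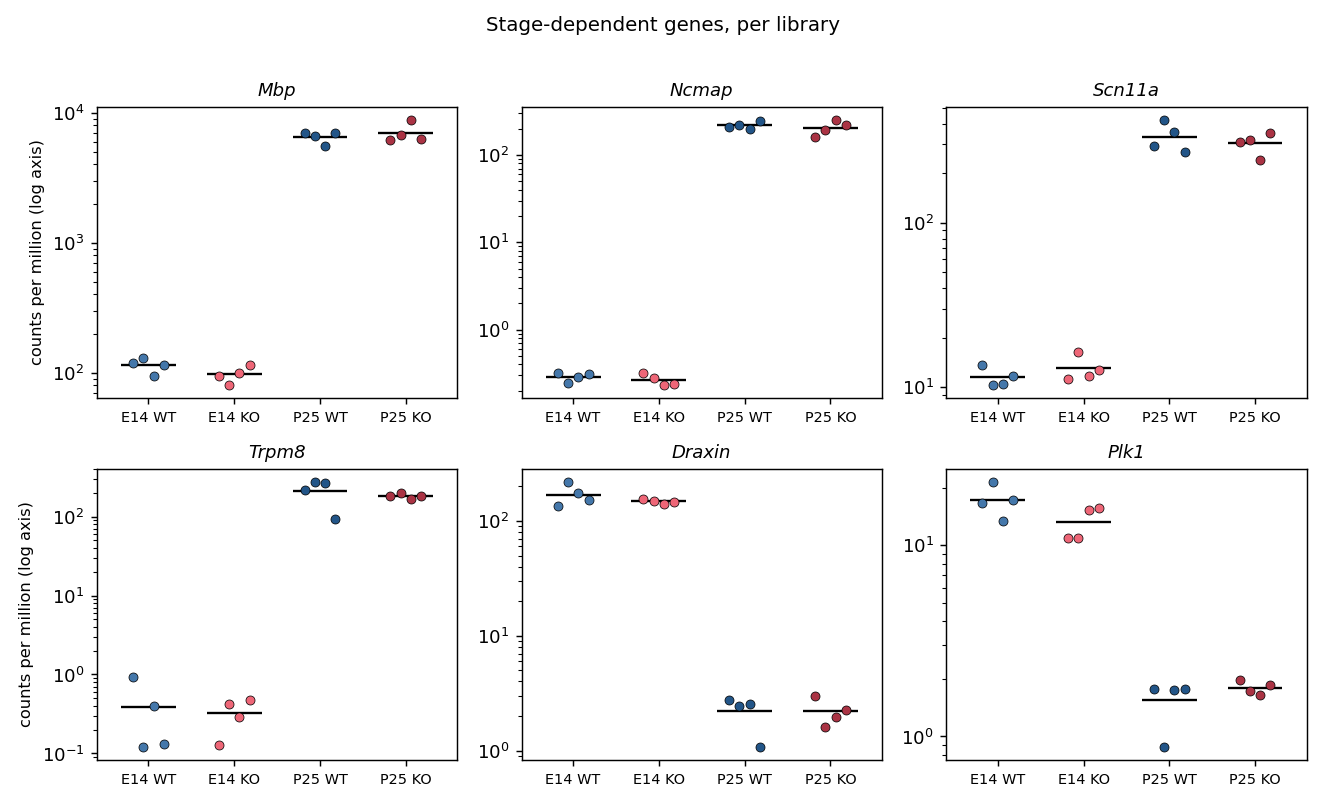
Levels in CPM (vertical log axes) of Mbp, Ncmap, Scn11a, Trpm8, Draxin and Plk1 in the 4 groups (horizontal axes). Points are libraries and bars are group means. In WT, Mbp moved from 114 to 6558, Trpm8 from 0.392 to 211 and Draxin from 170 to 2.21.

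Among growth and guidance genes more were called lower at P25 than higher. Cell cycle genes were called lower for 27 and higher for 2 of 32 (adjusted p = 9.35e-11, or 0.0674 with an estimated correlation), with the replication helicase subunit Mcm6 falling from 63.1 ± 6.25 to 8.53 ± 0.843 CPM and the mitotic kinase Plk1 from 17.1 ± 3.25 to 1.55 ± 0.442 CPM. Notch and neurogenesis factors were called lower for 14 of 18 (adjusted p = 8.35e-05, or 0.0427 with an estimated correlation). Axon guidance genes were called lower for 25 and higher for 4 of 41 (adjusted p = 0.000128, or 0.451 with an estimated correlation). Draxin fell from 170 ± 36.1 to 2.21 ± 0.767 CPM and the ephrin receptor Ephb2 from 199.6 ± 67.8 to 11.1 ± 1.61 CPM. Axon growth and injury response genes were called lower for 14 and higher for 7 of 28 (adjusted p = 0.0261, or 0.217 with an estimated correlation). Cytosolic ribosomal protein genes were called lower for 48 of 52 (adjusted p = 5.48e-06, or 0.544 with an estimated correlation), with Rps2 falling from 903 ± 209 to 321 ± 86.9 CPM. Nuclear genes of oxidative phosphorylation moved the other way, with 29 of 48 called higher (adjusted p = 0.0261, or 0.710 with an estimated correlation), among them Sdha from 163 ± 17.9 to 338 ± 25.8 CPM and Ndufb3 from 24.8 ± 4.23 to 68.6 ± 8.25 CPM. Matrix genes went both ways, with Col5a3 rising from 6.43 ± 1.83 to 170 ± 34.4 CPM and Tnc falling from 156 ± 38.6 to 6.05 ± 1.52 CPM.

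Among blood and immune genes, all 11 erythroid genes were called lower at P25 (adjusted p = 2.33e-10, or 0.0333 with an estimated correlation). The embryonic globins Hbb-y and Hba-x stood at 350.2 ± 86.9 and 66.8 ± 28.5 CPM at E14 and had no counts at P25, at least 12089-fold and 2200-fold lower. Trh and Reg3b also had no P25 counts, at least 1119-fold and 377-fold lower, and Ppp1r17 had 2924 counts at E14 and 1 at P25, a scaled ratio of 3806 with a counting interval of 682.5 to 150365. Macrophage genes were called higher for 15 of 20 (adjusted p = 0.00072, or 0.299 with an estimated correlation) and genes of neutrophils and mast cells for 5 of 5 (adjusted p = 0.0351, or 0.485 with an estimated correlation). Interferon-stimulated genes were called higher for 21 of 24 (adjusted p = 0.000172, or 0.495 with an estimated correlation), with Ifi27 rising from 5.66 ± 1.07 to 106 ± 37.8 CPM and Xaf1 from 0.443 ± 0.174 to 9.73 ± 3.76 CPM. In WT, 18 lists were called, 5 of them also with an estimated correlation. In these stage lists the counts of members adjusted over the list alone were the same as over all genes, except for 26 lower axon guidance genes, 21 higher receptor genes and 30 higher genes of oxidative phosphorylation.

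The KO ganglion went through a stage change of similar extent. In KO 9032 genes were called, 4622 higher and 4410 lower at P25. Of these 7702 were also called in WT, and 7699 of the shared genes changed in the same direction. Across the 15109 genes, which are not independent replicates, the log2 fold changes of the 2 genotypes had a Pearson r of 0.951. Myelinating Schwann cell genes were called higher for 26 of 26 in KO (camera adjusted p = 3.94e-46, or 0.00111 with an estimated correlation).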

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

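The tests of the 2 patterns weighed here were chosen after the result was seen, and the counts over other splits of the libraries were planned. Of 159 groups of 4 libraries examined for a library far from its group, 16 were singled out where 7.95 would be expected by chance.

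In the P25 KO group, replicate 4 lay far below the other libraries for Ccn1 (4.68 CPM against 179 to 362), Fosb (1.31 against 9.26 to 13.4), Egr1 (13.6 against 431 to 548) and the immediate early list mean (3.22 against 4.74 to 4.89 on the log2 CPM scale). Sex as the whole cause is argued against: with the Y-linked level as a covariate the median log2 fold change of the list was 0.74 (0.67 without it), and KO replicates 1 and 4 both lacked Y-linked reads. Handling or time between death and lysis stays open, since the labels hold 0 entries on dissection time or order. Loss of Nogo-A also stays open, since 3 of the 4 KO libraries had a list mean above all WT libraries and the remaining library alone excludes nothing. Handling and genotype cannot be told apart here, because immediate early genes may respond to either and no dissection record was at hand. The E14 libraries do not decide it either. Ccn1 was higher in all E14 KO libraries than in all E14 WT libraries, but the list was split, with 11 genes higher and 14 lower.

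At E14 another split of the libraries called more genes than genotype did. WT replicates 1, 3 and 4 with KO replicate 2, set against WT replicate 2 with KO replicates 1, 3 and 4, gave 811 called genes, 668 of them lower in the second set, which points to a structure of the samples other than genotype. Exchanged labels of WT replicate 2 and KO replicate 2 are argued against by genes chosen without these 2 libraries, called at P25 and apart by genotype in the other 6 E14 libraries: in 4 of 4, each of the 2 lay beyond all other libraries of the opposite genotype. Tissue of another kind in WT replicate 2 is argued against by a highest median deviation of 0.42 (log2), for the other tissues whose lists had at least 3 tested genes. The anterior pituitary and adipocyte lists had 1 tested gene each, so these tissues were not assessed. A trend on transcript GC content and length may account for most of the split: removing it left 124 called genes, and the 668 lower genes had a median GC content of 44.6% against 51.4% over all tested genes. What made the libraries differ in this way was not tested, and the 124 genes left stay unexplained.

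Other splits bear on each count of calls. At E14, 2 of the 35 splits gave as many genes as the real one, which called 3, and the highest of the others called 811. At P25, 2 of 35 gave as many, with 7 genes for the real split and 9 for the highest other, which set WT replicate 1 and KO replicates 1 to 3 against the rest. Chance is therefore not excluded for either count. For the lists, 7 of 35 splits at E14 gave as many (real 7, highest other 13) and 23 of 35 at P25 (real 10, highest other 22), so chance is not excluded there either. For the difference of the KO effect all 100 drawn splits gave at least the real count of 0, and the highest called 19. For the stage comparison 1 of 35 splits, the real one, gave as many genes in WT (9001, highest other 449) and in KO (9032, highest other 0). This share of 2.86% is the smallest that 35 splits can give. All other splits mix the stages within each group, which widens the spread and keeps their calls few. The share therefore does not exclude chance for these gene counts. The count of lists in WT was 18 for the real split and 17 for the highest other. Splits that exchange 1 library between the stages called 12 to 17 lists, so the count of lists says little about chance.

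Further libraries far from their group were E14 WT replicate 2 for Arhgap33os (1.65 CPM against 0.183 to 0.284), Xaf1 (0.183 against 0.512 to 0.550) and Chrna6 (0 against 0.0876 to 0.114), and E14 WT replicate 4 for Gbp3 (0.263 against 0). In E14 KO, replicate 3 stood apart for Itgam (0.583 CPM against 0.933 to 1.01) and replicate 2 for the immediate early list mean (2.62 against 2.47 to 2.49). In P25 WT, replicate 1 stood apart for Rassf10 (5.27 CPM against 4.00 to 4.13), replicate 2 for Plk1 (0.885 against 1.76 to 1.78), and replicate 4 for Draxin (1.08 against 2.44 to 2.78), Tnc (3.79 against 6.53 to 6.96) and Sv2b (241 against 348 to 368). P25 KO replicate 1 stood apart for Cox6b1 (194 CPM against 256 to 270.0).

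The KO effect differed between P25 and E14 for 8 lists by camera with the preset correlation, and for none with an estimated correlation. No member was called over all genes, and 9 immediate early genes were adjusted over the list alone. The median log2 difference of the effect (P25 minus E14) was 0.95 for immediate early genes (adjusted p = 8.88e-15, or 0.457 with an estimated correlation), -0.56 for cytosolic ribosomal proteins (3.93e-19 and 0.607), -0.40 for nuclear genes of oxidative phosphorylation (3.45e-13 and 0.607) and -0.77 for interferon-stimulated genes (3.48e-06 and 0.607). It was 0.33 for extracellular matrix (0.000437 and 0.607), -0.17 for heat shock and unfolded protein response (0.00856 and 0.457), 0.17 for cell cycle (0.0184 and 0.607) and 0.48 for erythroid genes (0.0336 and 0.607).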

How the results depend on the processing

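Offsets for transcript GC content and length, and robust dispersions, were chosen after seeing the data. The stage counts stayed within 1.5 times under all alternatives run. At E14 DESeq2 called 6 genes, and leaving out each library in turn gave 1 to 5. At P25 DESeq2 called 17, the fit with same-numbered ganglia summed 11, the GC and length offsets 11, the Y-linked covariate 4, the compared libraries only 3, and leaving out each library gave 3 to 14. For the difference of the KO effect DESeq2 called 8, and leaving out a library gave 0 to 7. Genes called at both stages numbered 1 with the compared libraries only and 1 to 4 on leaving out a library. On the whole of chromosome 11, 2 calls were found, both of Rnf167, where none lay within 20 Mb of Rtn4. Lists called numbered 0 at E14, 1 at P25 and 5 for the WT stage comparison with an estimated correlation, and 0, 0 and 39 with fry, which does not compare a list with other genes. Leaving out a library gave 3 to 9 lists at E14 and 8 to 14 at P25. The sign turned for 3 P25 results on leaving out a library: the median of the ribosomal list ran from -0.269 to 0.0549 (without WT replicate 4), that of the interferon list from -0.568 to 0.0829 and Usp18 from -2.26 to 0.13 (both without WT replicate 2). The cause was not tested for any of these, beyond the smaller number of libraries in the fits that leave some out.

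Replicate numbers did not pair the libraries: the deviations of same-numbered WT and KO libraries correlated at 0.03, -0.39, -0.04 and -0.24 at E14 and at 0.15, 0.15, -0.16 and 0.08 at P25. With the replicate block 2 genes were called at P25 in place of 7 and 2 at E14 in place of 3.

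Other scalings moved the median of all genes by less than 0.1 on the log2 scale. Genes near the floor, such as Gbp3, are limited by depth.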

Other observations

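The tests of the pattern in the last paragraph, and the genes it names, were chosen after the result was seen.

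In KO, the immediate early list was also called for the change with stage, with 19 of 25 genes called higher and 1 lower at P25 over all genes and the same numbers adjusted over the list alone (camera adjusted p = 0.00106, or 0.459 with an estimated correlation). In P25 KO replicate 4 the mean of this list was 3.22 against 4.74 to 4.89 in the other KO libraries. The receptor genes of sensory neurons were called higher for 21 and lower for 5 of 36 in KO, and the same adjusted over the list alone (adjusted p = 0.00026, or 0.0289 with an estimated correlation).

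On chromosome 7 the window from 26 to 36 Mb (GRCm38) held 6 of the 20 genes with an unadjusted p under 0.05 and the same sign at both stages (Fcgbp, Lgals7, Zfp30, Arhgap33os, Lgi4 and Cep89), and no window elsewhere held more than 1. With 10000 random shuffles of the genes this gave a permutation p of 0.00020, so a segment that differs between KO and WT animals may account for the change of Lgals7. A further 15 genes had an unadjusted p under 0.05 at both stages with opposite signs, and these were not part of the scan. DNA flanking Rtn4 is argued against for Lgals7, of which 0 copies lie on its chromosome, and stays open for Rnf167, 40.9 Mb away. Loss of Nogo-A itself stays open for Lgals7 and Rnf167 and was not tested, since KO animals may differ from WT animals in such segments as well.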
